A study of Mus musculus with 4 samples.

How the data were processed

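Total RNA had been extracted with TRIzol and depleted of ribosomal RNA before library preparation, per the labels' protocols, in 2 control and 2 differentiation libraries of mouse spermatogonial stem cells. Per the submitters' processing notes, reads were handled with HISAT2 and the GRCm38 build, and the annotation, the counting tool and the use of strand are not given in the sources used here. The series also concerns circular RNA, which was not analysed here. The deposited table held FPKM per feature and library, made by the authors. It also held the authors' log2 fold change, which differed from the log2 ratio of the group mean FPKM by a median of 0.00143 at a mean FPKM of at least 1. The deposited p-value and adjusted p of each feature came from a test that the sources used here do not name, and the adjusted p equalled a Benjamini-Hochberg adjustment of the p-value within 1.55e-15.

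Each FPKM was multiplied by the merged exonic length of its gene in GENCODE M21, which matched 31536 of 31600 identifiers. A scale per library was then fitted at which low values became whole numbers of fragments: between 96.4% and 96.5% of the features under 300 fragments were whole within 0.05 fragments. The scales were 19461700 and 20650200 fragments for control and 17772000 and 20363300 for differentiation. Libraries of a group differed by 1.60 to 2.33 times the Poisson variance, so they were kept as 2 replicates. Symbols came from the deposited table, and where a symbol had 2 features the one with the higher mean FPKM was used.

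The main test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with an intensity trend in the prior variance and group as the only term, on the 23138 features with a mean FPKM of at least 0.5. It was two-sided, with Benjamini-Hochberg adjusted p under 0.05. The test had 2 residual degrees of freedom and limma's prior added 2.14. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. The 26 gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation. Calls of long non-coding and protein-coding features were compared by direction with Fisher's exact test.

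The design, the lists and the rule for naming genes were fixed before the data were examined. The rule named the study genes, the 8 protein-coding genes with the largest change in each direction (higher group mean at least 5 FPKM, groups not overlapping), the 4 long non-coding RNAs likewise at 1 FPKM, and up to 4 members of each list with the smallest p. Genes outside it were named after their values were seen. Besides those marked as such, these are Rpl26, Lhx1, T, the features with ribosomal-RNA-like sequence, Lpin3, Edn1 and Usp18, which lie at named long non-coding RNAs, and the members of gene families chosen after seeing the data. Some members of the cholesterol biosynthesis list are not reported here by name. On simulated data of 23073 features with 200 changed, limma recovered 0% of features changed 1.25-fold, 18% at 1.5-fold, 46% at 2-fold and 82% at 4-fold, with 6 calls among unchanged features. In the real comparison 56.6% of tested features were called, which loosens the adjusted threshold. These rates therefore do not describe the power of that comparison. In a further simulation with 5049 calls, 3.76% were on unchanged features. The list test called 3 of 3 raised lists and 0 of 17 unchanged ones. Its simulated genes were drawn independently, so the preset correlation was not tested. A permutation test of medians gave p under 0.05 in 15 of 200 simulated null runs and in 10 of 10 with a shift.

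Alternatives were the pseudocount, the filter, the scaling between libraries, the prior variance, a replicate block, leaving out each library and a minimum fold change. A limma-voom fit on the recovered fragments was added after seeing the data, as was a comparison of classes restricted to features with a mean FPKM of 1 to 10. Further steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.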

Results

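RNA was measured in mouse spermatogonial stem cells, the germline stem cells of the testis, as control cells (2 libraries) and as cells of a differentiation group (2 libraries). Long RNA was sequenced after removal of ribosomal RNA, and the deposited table gave FPKM (fragments scaled to exon length and library depth) for 31600 features. The FPKM steps corresponded to 19461700 and 20650200 fragments in the control libraries and 17772000 and 20363300 in the differentiation libraries. Spearman's rho across features was 0.970 between the control libraries, 0.970 between the differentiation libraries and 0.857 to 0.861 between the groups (features are not independent replicates). The 3 features with ribosomal-RNA-like sequence, Gm26917, Gm42418 and CT010467.1, took 22.6% and 20.8% of the fragments in the control libraries and 18.3% and 17.7% in the differentiation libraries. The labels do not say whether the libraries of a group came from separate cultures or animals. The limma p-values of features thus hold no spread beyond that between these libraries, which may be technical. limma's camera at the preset correlation compares the genes of a list with the other genes tested. Its small p-values rest on the number of genes and do not measure a spread between libraries. Fisher's exact test and the permutation tests also compare genes, which are not independent replicates, and hold no spread between libraries.

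The comparison asks which RNAs differ between the group labelled differentiation and the control group. How the cells of the differentiation group were obtained, and after what time, is not given in the sources used here. The protein-coding genes with the largest increases are known from meiotic and postmeiotic germ cells. Ldhc, the testis lactate dehydrogenase, rose from 2.22 ± 0.331 FPKM (SD, n = 2) in control to 356 ± 4.64 FPKM (SD, n = 2) in differentiation. Rsph1, a radial spoke protein of the sperm tail, rose from 1.03 ± 0.043 to 103 ± 0.069 FPKM (SD, n = 2 per group), and Crisp2, a secretory protein of the acrosome and sperm tail, from 0.285 ± 0.085 to 64.0 ± 1.99 FPKM. Spata4, Mroh4, Cers3, Pdcl2 and Dkkl1 completed the 8 largest increases, with log2 fold changes of 6.11, 5.71, 5.40, 5.35 and 5.32. The largest decreases were in Igfbp5, a binding protein of insulin-like growth factors (10.9 ± 0.325 to 0.519 ± 0.191 FPKM, SD, n = 2 per group), Dlk1, Mgp, the steroidogenic enzyme Hsd3b1, the globin gene Hba-a1, the macrophage lysozyme Lyz2, Prss35 and Zbtb16. Zbtb16, a transcription factor needed to maintain spermatogonial stem cells, fell from 25.4 ± 0.023 to 3.85 ± 0.10 FPKM (SD, n = 2 per group).

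Of 23138 features tested, 6848 rose and 6246 fell at a limma adjusted p under 0.05, and 2244 and 1017 of these changed by at least 1 on the log2 scale. Groups did not overlap in 79.9% of the features, against 33.3% by chance. The authors' deposited table called 13360 features, 6943 higher and 6417 lower. Among the features tested here, 11554 were called in both tables, all in the same direction, where independent lists would share 6917. Both tests used the same libraries, so a large overlap in one direction was bound to arise and is no independent support.

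Genes of undifferentiated spermatogonia fell: 26 of 34 tested members fell and 1 rose (28 and 1 adjusted over the list alone), with a median log2 fold change of -0.996 (limma camera adjusted p = 5.97e-09; adjusted p = 0.207 with an estimated correlation). Besides Zbtb16, Sall4, a zinc finger factor of spermatogonial progenitors, fell from 29.2 ± 0.312 to 7.61 ± 0.035 FPKM, and Lin28a, an RNA-binding protein, from 17.7 ± 0.688 to 4.60 ± 0.145 FPKM (SD, n = 2 per group). The member that rose was Id4, a marker of the stem cell fraction, from 2.95 ± 0.078 to 12.4 ± 0.215 FPKM (SD, n = 2 per group), and it was named after its value was seen. Genes that respond to GDNF and FGF, the niche factors that sustain these cells, fell in 21 of 23 tested members and rose in 0 (21 and 0 adjusted over the list alone), with a median of -0.95 (limma camera adjusted p = 5.96e-08; adjusted p = 0.207 with an estimated correlation). These included Gfra1 and Ret, the GDNF receptor subunits, and their targets Bcl6b and Etv5, with log2 fold changes of -1.93, -1.83, -1.88 and -1.49. The lists share 6 tested members, Gfra1, Ret, Bcl6b, Etv5, Lhx1 and T, all of which fell, so they are not independent. Markers of fibroblasts fell in the same libraries, with a median of -1.28.

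Genes of differentiating spermatogonia fell in 11 of 19 tested members and rose in 4 (11 and 4 adjusted over the list alone), with a median of -0.38 (limma camera adjusted p = 0.0121; adjusted p = 0.224 with an estimated correlation). Kit, the receptor that marks differentiating spermatogonia, fell from 31.0 ± 0.861 to 7.69 ± 0.056 FPKM (SD, n = 2 per group). The 4 that rose were Gm4969, Tex15, Prdm9 and Scml2, named after their values were seen. Dmrt1 and Sohlh1, transcription factors of spermatogonia, and the DNA methyltransferase Dnmt3b had log2 fold changes of -2.11, -2.01 and -1.53. Fibroblast and leukocyte markers had lower medians than this list in the same comparison, -1.28 and -1.02. Stra8, the retinoic acid target required for entry into meiosis, was already at 237 ± 5.68 FPKM in control and fell to 140 ± 1.77 FPKM in differentiation (SD, n = 2 per group), and it was named after its value was seen. The retinoic acid response list went both ways: 9 of 21 tested members rose and 7 fell (9 and 7 adjusted over the list alone; limma camera adjusted p = 0.559). The retinoic acid hydroxylase Cyp26a1, the retinol transporter Stra6 and the retinol dehydrogenase Rdh10 rose by 1.30, 2.45 and 1.53 on the log2 scale, while the binding protein Crabp1 fell by 1.62.

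Meiotic genes rose: 31 of 37 tested members of the meiotic prophase list rose and 4 fell (31 and 4 adjusted over the list alone), with a median of 1.00 (limma camera adjusted p = 4.83e-07; adjusted p = 0.207 with an estimated correlation). Hspa2, the heat shock protein of pachytene spermatocytes, rose from 9.47 ± 0.150 to 159 ± 1.67 FPKM, and Hormad1, a protein of the meiotic chromosome axis, from 29.5 ± 0.747 to 135 ± 2.18 FPKM (SD, n = 2 per group). Meiob, which acts in meiotic recombination, rose by 2.95 on the log2 scale. Meioc, which acts in the progression of meiotic prophase, rose from 32.7 ± 0.370 to 101 ± 0.303 FPKM (SD, n = 2 per group). The 4 members that fell were Rec8, Tex11, Mei4 and Rec114, named after their values were seen. The germ cell and piRNA pathway list rose in 23 of 29 tested members and fell in 4 (23 and 4 adjusted over the list alone), with a median of 0.79 (limma camera adjusted p = 1.88e-05; adjusted p = 0.207 with an estimated correlation). Piwil1, the PIWI protein of pachytene piRNAs, rose from 1.40 ± 0.176 to 62.7 ± 0.931 FPKM (SD, n = 2 per group), and Tdrd6, a tudor protein of the chromatoid body, by 4.27 on the log2 scale. The 4 that fell were Mov10, Tex19.1, Fkbp6 and Dnd1, named after their values were seen. Of the spermatid list, 15 of 21 tested members rose and 0 fell (15 and 2 adjusted over the list alone), with a median of 0.94 (limma camera adjusted p = 3.34e-04; adjusted p = 0.338 with an estimated correlation). Besides Ldhc, these included the acrosomal protease Acr, the acrosomal protein Zpbp2 and the transcription factor Crem, at 2.95, 2.81 and 1.85 on the log2 scale. Of the 30 members of the spermatid list 28 were in the deposited table, and 21 reached the mean of 0.5 FPKM needed for testing. The others in that table were low or absent in both groups together, so the share and the median do not cover the whole list.

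**Figure D1:**
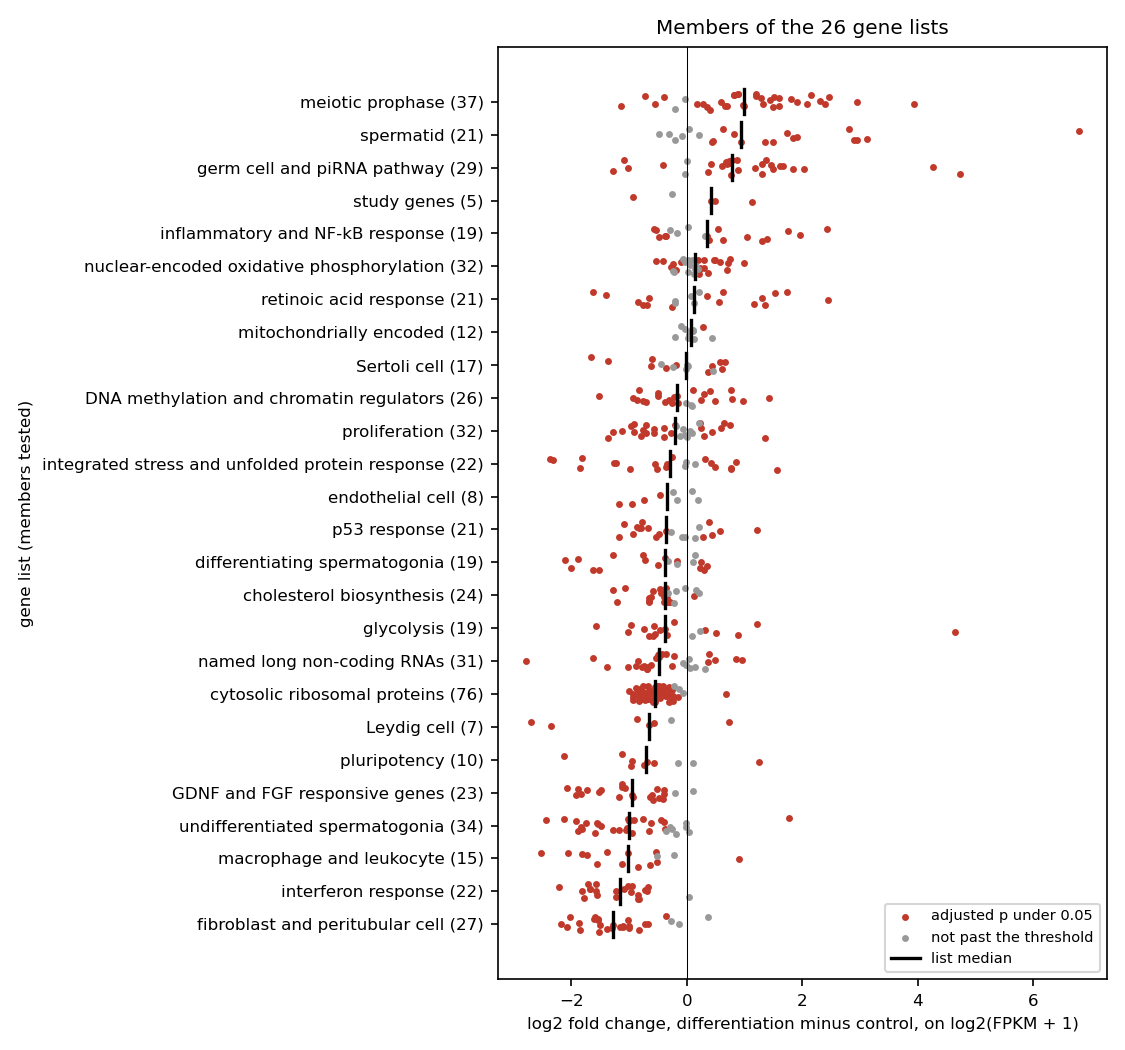
Each point is a tested member of a gene list, placed by its log2 fold change of differentiation minus control on log2(FPKM + 1), in red where the limma adjusted p was under 0.05 and grey otherwise; black bars are list medians and numbers in brackets are members tested. The meiotic prophase list has the highest median, 1.00, and the fibroblast and peritubular cell list the lowest, -1.28.

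Markers of other testis cells were detected in control, and 3 of the 5 lists of such markers fell in differentiation. The fibroblast and peritubular cell list fell in 24 of 27 tested members and rose in 0 (25 and 1 adjusted over the list alone), with a median of -1.28 (limma camera adjusted p = 1.56e-09; adjusted p = 0.207 with an estimated correlation). Col1a1, a collagen of connective tissue, fell from 75.7 ± 3.88 to 20.4 ± 0.733 FPKM, and Thbs1, an adhesive glycoprotein, from 133 ± 1.10 to 43.9 ± 2.41 FPKM (SD, n = 2 per group). The macrophage and leukocyte list fell in 12 of 15 tested members and rose in 1 (12 and 1 adjusted over the list alone), with a median of -1.02 (limma camera adjusted p = 8.42e-05; adjusted p = 0.207 with an estimated correlation), and Lyz2 fell from 28.6 ± 1.14 to 4.16 ± 0.400 FPKM (SD, n = 2 per group). The member that rose was Aif1, named after its value was seen. The Leydig cell list fell in 5 of 7 tested members and rose in 1 (6 and 1 adjusted over the list alone), with a median of -0.66 (limma camera adjusted p = 0.0220; adjusted p = 0.454 with an estimated correlation). Cyp11a1, which starts steroid synthesis, fell by 2.35 on the log2 scale, while Star, the carrier of cholesterol into mitochondria, rose by 0.73. The Leydig call was lost among features with a mean of at least 2 FPKM (limma camera adjusted p = 0.0544). Sertoli cell markers went both ways, with 5 of 17 tested members higher and 6 lower (5 and 6 adjusted over the list alone) and a median of -0.02 (limma camera adjusted p = 0.466). Of 8 endothelial markers tested, 4 fell and 0 rose (3 and 0 adjusted over the list alone; limma camera adjusted p = 0.0553), and this list passed without differentiation replicate 1 (limma camera adjusted p = 0.0476) and under 3 other settings.

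Cytosolic ribosomal protein genes fell together: 72 of 76 tested members fell and 1, Rpl26, rose (72 and 1 adjusted over the list alone), with a median of -0.54 (limma camera adjusted p = 7.87e-14; adjusted p = 0.207 with an estimated correlation). Rpsa, a protein of the small subunit, fell from 142 ± 0.914 to 70.8 ± 1.16 FPKM, and Rpl4, of the large subunit, from 255 ± 4.92 to 143 ± 1.59 FPKM (SD, n = 2 per group). Ribosomal protein genes have many processed pseudogenes, and how the authors divided reads between such copies is not given in the sources used here. Interferon response genes fell in 21 of 22 tested members and rose in 0 (21 and 0 adjusted over the list alone), with a median of -1.16 (limma camera adjusted p = 1.33e-08; adjusted p = 0.207 with an estimated correlation), and the antiviral membrane protein Bst2 fell from 44.2 ± 0.133 to 14.4 ± 0.197 FPKM (SD, n = 2 per group). Cholesterol biosynthesis genes fell in 17 of 24 tested members and rose in 1 (17 and 1 adjusted over the list alone), with a median of -0.38 (limma camera adjusted p = 1.66e-04; adjusted p = 0.207 with an estimated correlation). Dhcr7, the enzyme of a final step of cholesterol synthesis, fell by 1.21 on the log2 scale. The pluripotency list fell in 7 of 10 tested members and rose in 1 (7 and 1 adjusted over the list alone), with a median of -0.71 (limma camera adjusted p = 0.0207; adjusted p = 0.251 with an estimated correlation). Pou5f1, a pluripotency factor also present in spermatogonia, fell from 5.74 ± 0.873 to 0.542 ± 0.118 FPKM (SD, n = 2 per group), and the call of this list was lost among features with a mean of at least 2 FPKM (limma camera adjusted p = 0.0858). The member that rose was Zfp42. The fibroblast and leukocyte markers fell in the same libraries as these 4 lists, in which the ribosomal-RNA-like features also took a smaller share of fragments.

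The following 8 lists did not pass as lists. Of the proliferation list, 8 of 32 tested members rose and 16 fell (8 and 17 adjusted over the list alone; limma camera adjusted p = 0.0693), and the list passed with no filter on low values, after quantile normalization and with limma-voom (limma camera adjusted p = 0.0469, 0.0476 and 0.0281). The replication helicase genes Mcm2 and Mcm4 fell by 1.36 and 1.12 on the log2 scale, while the mitotic kinase Aurka rose by 1.35. In the p53 response list 5 of 21 tested members rose and 11 fell (5 and 11 adjusted over the list alone; limma camera adjusted p = 0.111). In the integrated stress and unfolded protein response list 7 of 22 rose and 12 fell (8 and 12 adjusted over the list alone; limma camera adjusted p = 0.152). Asns, Phgdh and Psat1, enzymes of asparagine and serine synthesis, fell by 2.32, 2.36 and 1.82 on the log2 scale, and Sdf2l1, an endoplasmic reticulum chaperone component, rose by 1.57. In the glycolysis list 5 of 19 rose and 12 fell (5 and 12 adjusted over the list alone; limma camera adjusted p = 0.152). The glucose transporter Slc2a3 rose from 2.88 ± 0.264 to 96.0 ± 0.244 FPKM, while Gpi1 fell from 34.6 ± 0.276 to 16.5 ± 0.035 FPKM (SD, n = 2 per group). In the inflammatory and NF-kB list 10 of 19 rose and 5 fell (11 and 6 adjusted over the list alone; limma camera adjusted p = 0.196). In the nuclear-encoded oxidative phosphorylation list 14 of 32 rose and 6 fell (14 and 6 adjusted over the list alone; limma camera adjusted p = 0.152), and in the list of DNA methylation and chromatin regulators 9 of 26 rose and 14 fell (9 and 14 adjusted over the list alone; limma camera adjusted p = 0.324). Of the mitochondrially encoded genes, 1 of 12 rose and 0 fell (0 and 0 adjusted over the list alone; limma camera adjusted p = 0.629). That gene was mt-Nd2, whose call was lost without control replicate 1 or 2 (limma adjusted p = 0.0621 and 0.0818).

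**Figure D2:**
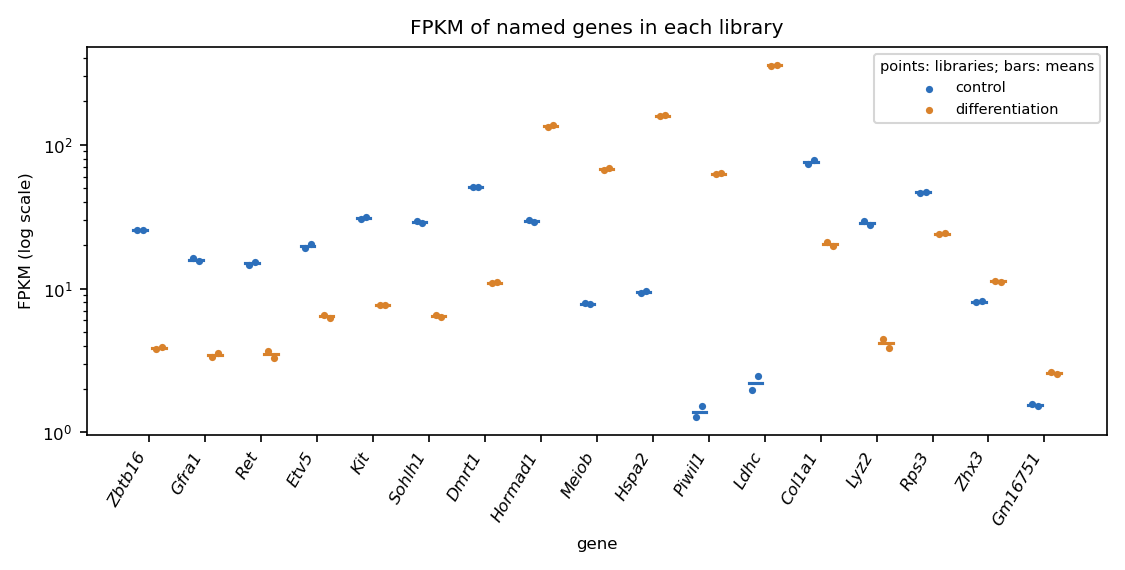
FPKM on a log axis of 17 named genes in the 2 control libraries (blue) and the 2 differentiation libraries (orange); points are libraries and bars are group means. The libraries of each group lie apart from those of the other for every gene drawn, from 1.55 against 2.60 FPKM for Gm16751 to 2.22 against 356 FPKM for Ldhc.

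The series concerns the long non-coding RNA Gm16751, the transcription factor gene Zhx3 and the ribosomal protein gene Rps3. Gm16751 (ENSMUSG00000085303) was at 1.55 ± 0.044 FPKM in control and 2.60 ± 0.052 FPKM in differentiation (SD, n = 2 per group), a log2 fold change of 0.50 (SE 0.09; limma adjusted p = 0.0110), higher in both differentiation libraries than in either control library. These values rest on 52 and 53 fragments in control and 79 and 88 in differentiation. On these recovered fragments the log2 fold change was 0.74, with a standard error of 0.24. That standard error takes a spread of 1.80 times the Poisson variance. The limma SE of 0.09 is on the log2(FPKM + 1) scale and does not take the fragment counts into account, so the limma p-value may overstate the certainty of this change. Leaving out any 1 of the 4 libraries ended the call, with limma adjusted p from 0.0515 to 0.0600 and log2 fold changes from 0.48 to 0.51. Zhx3 (ENSMUSG00000035877) rose from 8.10 ± 0.094 to 11.2 ± 0.127 FPKM (SD, n = 2 per group), a log2 fold change of 0.42 (SE 0.04; limma adjusted p = 2.16e-03). Its paralog Zhx1 rose by 1.13 on the log2 scale (limma adjusted p = 2.49e-04), and Zhx2 had a log2 fold change of -0.26 (limma adjusted p = 0.0905), which passed after quantile normalization, median centring and limma-voom (limma adjusted p = 0.0428, 0.0462 and 0.0171). Rps3, a small-subunit ribosomal protein, fell from 46.5 ± 0.693 to 24.0 ± 0.192 FPKM (SD, n = 2 per group; limma adjusted p = 1.70e-04), as did most of the ribosomal protein list. As a list, the study genes had 3 of 5 members higher and 1 lower (3 and 1 adjusted over the list alone; limma camera adjusted p = 0.559).

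On GRCm38 chromosome 2, GENCODE M21 places Zhx3 at 160748708 to 160872998 and Gm16751 at 160840836 to 160888028, both on the minus strand. Gm16751 has 3 exons. The third, at 160840836 to 160841536, lies in a Zhx3 intron and holds 701 of the 1685 exonic bases, and no exonic base is shared with a Zhx3 exon. The exon of 899 bases at 160887130 to 160888028 lies within Lpin3, a lipin gene on the plus strand, and shares no base with a Lpin3 exon. Unspliced Zhx3 RNA lies on the same strand as Gm16751, so even counting by strand would not separate it from fragments of that Gm16751 exon. Whether the authors counted reads by strand is not given in the sources used here, so unspliced Lpin3 RNA cannot be separated either. Lpin3 was at 6.67 ± 0.484 FPKM in control and 5.81 ± 0.004 FPKM in differentiation (SD, n = 2 per group; limma adjusted p = 0.0961). The processed pseudogene Gm11447, on the plus strand, lies in the same Zhx3 intron as the third Gm16751 exon and shares no exonic base with Gm16751. It rose from 2.87 ± 0.332 to 5.125 ± 0.449 FPKM (SD, n = 2 per group, limma adjusted p = 7.95e-03) and was named after its value was seen. Whether unspliced Zhx3 RNA was counted in it was not tested.

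**Figure D3:**
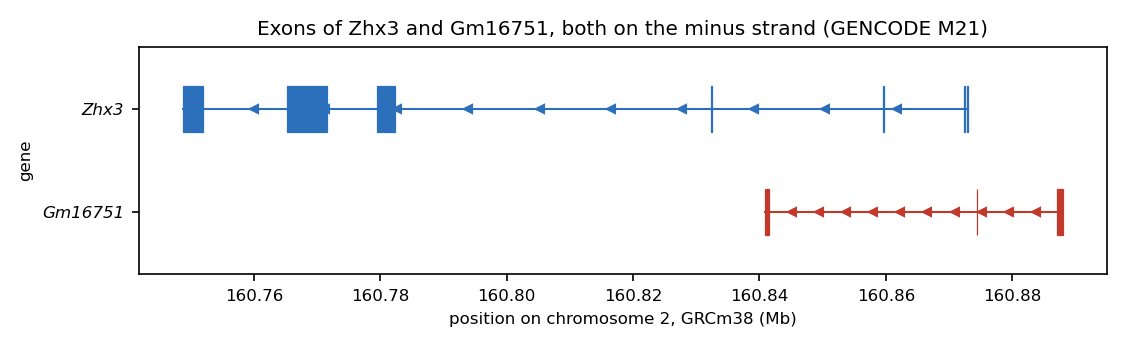
Map of Zhx3 (blue) and Gm16751 (red) on GRCm38 chromosome 2, with position in Mb on the x axis, boxes for merged exons and arrowheads for the direction of transcription. The exon of Gm16751 at 160840836 to 160841536 lies in a Zhx3 intron.

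The table also allowed long non-coding and protein-coding RNAs to be compared. Of 3435 long non-coding RNAs tested, 1042 rose and 634 fell, and of 14397 protein-coding genes 4680 rose and 4901 fell. The odds of a called feature being higher were greater among long non-coding RNAs, with an odds ratio of 1.72 (95% interval 1.55 to 1.92; Fisher's exact test, two-sided, p = 5.57e-24, across genes, which are not independent replicates). Among lincRNAs 388 rose and 164 fell, among antisense RNAs 457 and 333, among processed transcripts 119 and 101, and among sense intronic RNAs 34 and 31. The excess was not particular to long non-coding RNAs: of the features in neither class, 1126 rose and 711 fell. The largest increases were in Gm10505 (0.154 ± 0.127 to 67.1 ± 0.213 FPKM, SD, n = 2 per group), Gm14244, 1700008K24Rik and 1700009C05Rik, at 5.89, 5.86, 5.67 and 5.44 on the log2 scale. The largest decreases were in Gm19553, H19, AC154635.1 and Gm44148, at -2.83, -2.78, -2.19 and -2.17. Of these, Gm19553 shares 317 of its 494 exonic bases with Pou5f1, AC154635.1 shares 35 of 400 with Edn1, and Gm44148 shares 124 of 316 with Usp18, each on the opposite strand. Pou5f1, Edn1 and Usp18 fell by 2.12, 2.24 and 1.58 on the log2 scale, so without strand these pairs cannot be told apart. H19, an imprinted RNA, fell from 24.0 ± 0.215 to 2.65 ± 0.649 FPKM (SD, n = 2 per group). The list of named long non-coding RNAs fell in 20 of 31 tested members and rose in 5 (20 and 5 adjusted over the list alone), with a median of -0.47 (limma camera adjusted p = 8.31e-03; adjusted p = 0.207 with an estimated correlation). Its members Gas5 and Snhg1, hosts of small nucleolar RNAs, fell by 0.69 and 0.88 on the log2 scale. The call of this list was lost among features with a mean of at least 2 FPKM (limma camera adjusted p = 0.0757). Fibroblast and leukocyte markers fell in the same libraries, with medians of -1.28 and -1.02.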

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

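The limma count of 13094 changed features ranged from 10114 to 14462 over the other pseudocounts, filters, scalings and prior variances and the limma-voom fit added after seeing the data, and every feature shared with the main calls kept its direction. Leaving out 1 library, where the lone library of its group is assumed to vary like the others, gave 9438 to 10217. A minimum log2 change of 1 left 3261 features, 2244 higher and 1017 lower, by its own construction. The share of calls that were higher was 52.3% as deposited, 60.3% after rescaling to the same total and 43.3% after quantile normalization. With the replicate number as a block, 12298 features were called (6510 higher, 5788 lower); deviations of same-numbered libraries from their group means correlated at -0.000408 across features, and nothing in the labels pairs them. Of 14 lists called by limma's camera, 0 passed with an estimated correlation, where 4 had an unadjusted p under 0.05 and the smallest adjusted p was 0.207; that test uses the 2 residual degrees of freedom alone. limma's fry asks whether a list's genes move on balance one way without comparing them with other genes. For these 14 lists limma's fry gave p from 5.42e-05 to 2.91e-03. For the uncalled lists limma's fry gave p from 1.01e-04 to 0.0273, except glycolysis and the mitochondrially encoded genes, which stayed above 0.05. It therefore does not set the called lists apart from the others. The odds ratio of long non-coding against protein-coding calls lay between 1.65 and 1.98 over 16 alternatives and was 1.95 at a mean FPKM of 1 to 10. Among single genes named by the rule, 7 changed their side of the threshold under some alternative, the minimum fold change aside, and 0 changed direction; for Gm16751 the alternatives other than leaving out a library or requiring a minimum fold change kept the call (limma adjusted p 0.0048 to 0.0303), and its log2 fold change of 0.50 lies below that minimum of 1. Depth limits the weak features: 9208 had fewer than 20 fragments in each library.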

Other observations

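The tests on gene families, on autosomal copies of X-linked genes, on Gm16751 against Zhx3 and on the fibroblast and leukocyte lists were chosen after the results were seen. Genes of the axoneme, the motor core of the sperm tail, were higher in differentiation. Of 53 tested genes with Cfap, Dnah, Rsph, Tekt or Drc symbols, 49 rose and 1 fell, with a median log2 fold change of 1.85 (permutation test of medians across genes, Benjamini-Hochberg p over the 4 families tested = 0.00002). Tekt1 and Tekt4, 2 of these genes, are also in the spermatid list. Dnah8, a dynein heavy chain of sperm, rose from 13.4 ± 0.374 to 189 ± 4.61 FPKM (SD, n = 2 per group). Histone genes with Hist1h, Hist2h, Hist3h or Hist4h symbols, the symbols of replication-dependent histones, fell in 39 of 65 and rose in 11. Their median was -0.51 (permutation test, adjusted 0.00002), and these genes have near-identical copies whose reads the counting could split. The symbols also take in testis histones, which were among those that rose. Hist1h2ba, the testis-specific histone H2B, rose from 437 ± 8.76 to 1133 ± 16.1 FPKM (SD, n = 2 per group). Hist1h1t, the testis histone H1, rose from 18.1 ± 0.554 to 316 ± 13.7 FPKM (SD, n = 2 per group). Collagens fell in 19 of 34 and rose in 7 (median -0.51, permutation test, adjusted 0.00021). This partly restates the fibroblast result, since 7 of these collagens are in that list; of the 27 others 12 fell and 7 rose. The ADAM family had 7 of 19 higher and 6 lower (permutation test, adjusted 0.0926).

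The 4 haemoglobin genes listed all fell, Hbb-bs from 415 ± 9.16 to 81.4 ± 7.58 FPKM (SD, n = 2 per group). Long non-coding RNAs that share a bidirectional promoter rose in 40 and fell in 3 of 89 tested, against 1002 and 631 in the other long non-coding classes. This class was singled out after its value was seen, as the one of the 15 larger annotated classes other than protein-coding with the greatest share of higher calls, and no test is given.

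The median log2 fold change of 537 X-linked protein-coding genes was -0.359, below that of each of the 19 autosomes (-0.11 to 0.07). A permutation test of medians across genes gave p = 0.00001, the smallest 100000 permutations can give. Of the X-linked genes, 297 fell while 59 rose. The tables argue against the expression level of X-linked genes as the cause, since 0 of 10000 autosomal lists matched on mean FPKM had a median as low (lowest -0.14). Lower transcription of the X in later meiotic cells is a candidate explanation that rests on this median alone, and a loss of spermatogonia, which express many X-linked genes, was not tested. Autosomal retrocopies of X-linked genes do not decide it: their log2 fold changes lay above those of their X-linked parents by a median of 1.358 over 10 pairs, but 9 parents were themselves below 0 and the pairs were chosen for copies known in meiosis. Of the 10 copies 7 rose, 1 fell and 2 did not pass (limma adjusted p under 0.05).

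Gm16751 and Zhx3 rose together at a locus they share. On recovered fragments the log2 fold of Gm16751 exceeded that of Zhx3 by 0.274, with a standard error of 0.244. That lies within the 2 standard errors set for unspliced Zhx3 RNA as the cause, but the counts are few. More fragments would not settle it, since the Zhx3 fold is that of its exons and unspliced Zhx3 RNA was not measured. Only 701 of the 1685 exonic bases of Gm16751 lie in the Zhx3 intron. Unspliced Zhx3 RNA in that exon therefore cannot be told apart from a change in Gm16751 itself. Across the table, 250 pairs joined a long non-coding RNA to a same-strand gene with an intron that holds an exon of that RNA. An RNA could enter more than once. Fold changes of the RNA followed those of the gene (Spearman's rho 0.706 across pairs). This rho exceeded by 0.312 that in 369 neighbouring same-strand pairs within 20 kb that do not overlap (bootstrap SE 0.0618). Reads of the enclosing gene counted in the nested one are consistent with this, a test set before its result was seen. However, 626 pairs on opposite strands gave a similar rho of 0.699, so counting without strand or shared regulation of a locus may act as well, and neither was tested.

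The fibroblast and leukocyte lists fell. Even dilution of every other cell type by later germ cells would lower Sertoli markers alike, but the Sertoli median lay 1.258 above that of fibroblasts (permutation p across genes = 0.00008). However, some Sertoli markers are also known in germ cells, and the list was mixed. Of its members 6 fell, among them Inhbb and Inha (log2 fold changes of -1.66 and -1.37), and 5 rose, among them Clu (0.36). Its median alone therefore does not decide on dilution. Both lists stayed low under the 3 other scalings, where the higher of their medians was -0.977. Those scalings moved the median of all features from 0.0121 only to 0.0863, -0.0855 and -0.0624. They could not have brought either list to 0, so a larger difference in scale between the groups stays undecided. The number of such cells and their expression per cell both stay open, since no cell counts or single-cell values were used here.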
